A study of Homo sapiens with 12 samples.

How the data were processed

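Messenger RNA of the human cell line K562 was sequenced from 12 libraries in 3 groups of 4: untreated cells, cells given 2 mM alpha-ketobutyrate (AKB) and cells given 2 mM pyruvate, both for 24 h. Groups and replicate numbers were taken from the sample labels, which tie every column of the count table to 1 library. The labels do not say that the 4 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

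Per the labels' protocols, the libraries were made from poly(A)-selected RNA with a kit that fragments the RNA before reverse transcription. The submitters' processing notes name Salmon 1.2.1, R 3.6.3 and DESeq2 1.26.0. The genome build, the annotation and the settings of these tools are not given in the sources used here. The deposited counts are estimated counts per gene that the authors made with Salmon, per the submitters' processing notes. The table holds 17786 Ensembl gene identifiers and 12 count columns, its smallest total over the 12 libraries is 10, and the values are whole numbers. As estimated counts need not be whole, they were rounded before the count test, which changed no value. The authors also deposited 3 tables of their own comparisons with the columns that DESeq2 writes. Per the file headers, these tables give a mean normalised signal per gene (baseMean), a log2 fold change with its standard error on the log2 scale, a p-value and an adjusted p-value. Their fold changes put the first-named group over the second. Values from them are named as the authors' and were not tested again.

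Total counts per library ran from 15353200 to 21301073. Levels are given as counts scaled to library size (CPM). Gene symbols were matched by Ensembl identifier for 16933 identifiers (95.2%). GC content and coordinates came from GENCODE release 29 on GRCh38, with the longest transcript standing for each gene, and 16904 identifiers (95.0%) had a value. Since the authors' build is not given in the sources used here, the coordinates are those of GENCODE 29.

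The comparisons used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr by group with its default minimum count of 10, which left 13598 genes and removed the rest of the 17786. Of the genes tested, 12714 had a usable symbol and 884 did not. Library sizes were scaled by TMM, and edgeR's quasi-likelihood test was fitted to all 12 libraries with 1 term per group and no covariate, so that the 3 groups shared 1 estimate of the spread. The contrasts tested were AKB against untreated, pyruvate against untreated and AKB against pyruvate. A gene was called at an adjusted p below 0.05 by the Benjamini-Hochberg method over all genes tested in that contrast. Every adjusted p of a gene comes from edgeR's quasi-likelihood test unless another tool is named. The standard error of a log2 fold change is its size over the square root of the F statistic, and 95% intervals use the t distribution with the test's degrees of freedom. Mean levels ± SD of 4 libraries are on the TMM-scaled library sizes.

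Before the data were examined, 34 gene lists were fixed from general knowledge. The 30 lists with at least 5 measured members were tested with limma camera on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists. Every adjusted p of a list comes from limma camera. For the lists described the number of members called over all genes is given with the number called when p-values were adjusted over the list alone. List calls were repeated with an inter-gene correlation estimated from the data.

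The genes named were chosen by a rule written before the data were examined. They are, per contrast, the 10 largest rises and the 10 largest falls by log2 fold change (5 and 5 for AKB against pyruvate) among called genes with a symbol, at least 5 CPM in the higher group and no overlap between the 4 libraries of each group. Added to these are up to 4 members of each list described, those with the smallest adjusted p, and further genes fixed by name, some of which were not analysed here. The genes HBA1, HBA2, GPT2, SLC7A5, SMOX and HEXIM1 lie outside this rule and were named after their values were seen.

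Both treatments were compared with the same 4 untreated libraries. Their fold changes were set beside 20 simulated data sets in which no group changed, and beside fits with the untreated libraries split into 2 and 2, in all 6 ways. A score of the ATF4 list per library, the mean log2 CPM of its members, was compared between groups by a two-sided exact permutation test over the 70 assignments of 8 libraries.

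The alternatives fixed before the data were examined were DESeq2's size factors in edgeR, library size alone, no filter on low counts, a mean of at least 1 CPM, DESeq2's Wald test, limma-voom, the replicate number as a block, the 8 libraries of each contrast alone, each library left out in turn, and a test against a fold change of 1.2. For lists they were the estimated correlation, fry, the block, other size factors and no filter. After the data were examined, 3 alternatives were added because 2 pyruvate libraries stood apart along GC content. They were a GC-content offset (loess of each library's log2 CPM deviation on transcript GC, span 0.3), the 2 pyruvate libraries left out, and the GC-content offset with the replicate block. The tests of lists without the members they share with the ATF4 list, and the score of the ATF4 list, were also chosen after the data were examined.

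The scripts were tested on simulated counts drawn from the untreated means, the real library sizes and the fitted dispersions, with 100 genes changed 1.5-fold and 100 changed 2-fold in each treated group, and edgeR kept 13297 genes of these. For AKB against untreated, edgeR recovered 60% of the 1.5-fold and 94% of the 2-fold changes, and 4.17% of its calls were false. For pyruvate against untreated it recovered 60% of the 1.5-fold and 88% of the 2-fold changes, with 4.52% false. In the same simulations DESeq2's Wald test gave 17.8% false calls in each comparison among 13590 genes. The simulated counts used edgeR's dispersions, equal in all groups, and held no GC trend. These rates may therefore not hold for the real data, above all for the pyruvate group. For a simulated AKB against untreated comparison with 1 shifted list of 30, camera gave that list an adjusted p of 3.91e-20 and called 0 others. The simulated genes were drawn independently of each other. That 0 therefore does not measure how often camera calls lists falsely when genes vary together, as they do along GC content here. The deposited files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.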

Results

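K562 cells, a line from chronic myelogenous leukaemia that expresses embryonic and fetal globin genes, were compared after 24 h with 2 mM AKB, with 2 mM pyruvate or without either (n = 4 libraries per group). AKB and pyruvate are 2-oxo acids that differ by a single methylene group, and lactate dehydrogenase can reduce both with NADH. Of 13598 genes tested, 186 were higher and 82 lower with AKB than in untreated cells, and 139 were higher and 126 lower with pyruvate (adjusted p below 0.05 by edgeR's quasi-likelihood test). The p-values measure only the spread between these libraries, which the labels do not describe as separate cultures.

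The largest difference between libraries ran along the GC content of the genes and set pyruvate replicates 3 and 4 apart. Their log2 CPM rose by 0.333 and 0.359 per 10 percentage points of transcript GC relative to the mean of all libraries, against −0.15 to 0.00249 in the other 10. The first principal component of 9550 genes held 53.8% of the variance, and its gene loadings had a Spearman correlation of 0.833 with GC content. These libraries were also the deepest (19.9e6 and 21.3e6 counts against 15.4e6 to 18.4e6). In them the alpha-globin gene HBA2 stood at 510 and 504 CPM against 119 to 264 CPM in the others. Its near-identical copy HBA1 stood at 1564 and 1418 CPM against 1403 to 1677 CPM, so the share of each copy is uncertain. Counts of genes are therefore also given with a GC-content offset and with pyruvate replicates 3 and 4 left out, both chosen after seeing the data.

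**Figure D1:**
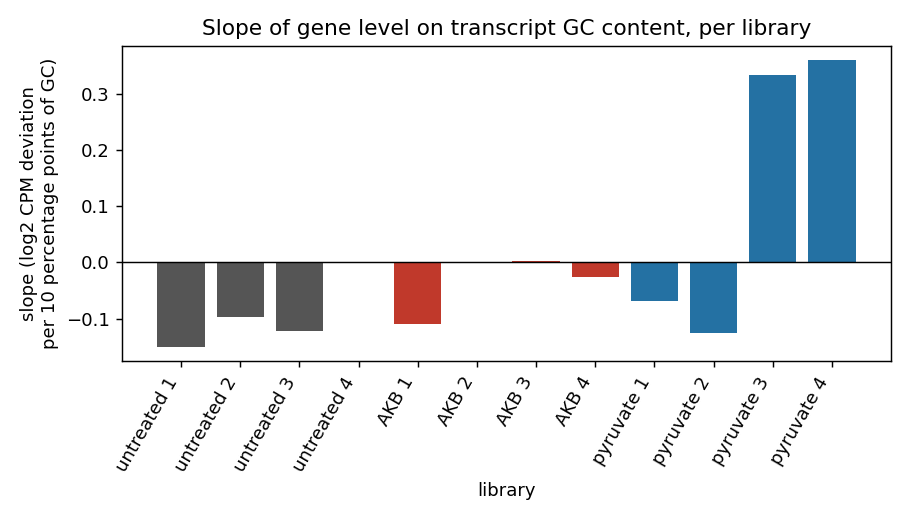
Slope of each library's log2 CPM deviation on transcript GC content (vertical axis, log2 per 10 percentage points) for the 12 libraries. Pyruvate replicates 3 and 4 stood at 0.333 and 0.359.

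The mRNAs of the amino acid response were lower with AKB. The transcription factor ATF4 induces this programme when amino acids run short. The serine synthesis enzyme PSAT1 fell from 206 ± 7.32 to 104 ± 3.64 CPM (log2 fold change −0.99, SE 0.081, adjusted p = 0.000378), and asparagine synthetase, ASNS, from 385 ± 26.9 to 206 ± 2.33 CPM (−0.90, SE 0.095, adjusted p = 0.000914). ATF4 itself fell 1.41-fold (241 ± 4.03 against 341 ± 11.3 CPM, adjusted p = 0.0023). Of 36 members of the ATF4 list, 22 fell and 0 rose (31 fell when adjusted over the list alone). All 36 estimates were below 0, with a median log2 change of −0.50 (camera adjusted p = 5.59e-41, and 1.36e-05 with an estimated correlation). The same comparison gave 667 higher and 475 lower genes with the GC-content offset, and without pyruvate replicates 3 and 4, 677 and 601. All 186 and 82 first calls were among those made without these libraries, and 182 and 82 among those made with the offset.

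Several of the 10 largest falls with AKB were in this list. CHAC1, which degrades glutathione, fell 2.82-fold (3.23 ± 1.05 against 9.14 ± 0.895 CPM, adjusted p = 0.0078). DDIT4, an inhibitor of mTORC1 signalling, fell 2.67-fold to 62.4 ± 3.34 CPM (log2 −1.42, SE 0.19, adjusted p = 0.0023). INHBE, an activin subunit gene outside the list, fell 2.06-fold, and within it the stress transcription factor ATF3 fell 1.93-fold and the cystine carrier SLC7A11 1.71-fold (60.5 ± 3.59 against 103 ± 8.13 CPM, adjusted p = 0.00646). Smaller falls were those of cystathionine gamma-lyase, CTH (1.63-fold), the amino acid carrier SLC1A4 (1.46-fold), the tryptophanyl-tRNA synthetase WARS1 (1.43-fold) and the pseudokinase TRIB3 (1.37-fold, adjusted p = 0.00806). DDIT3, which encodes CHOP, stood at 18.9 against 23.9 CPM (adjusted p = 0.123), and the log2 difference of GDF15 was −0.28 (adjusted p = 0.518). The ASNS pseudogene ASNSP1 (1.81-fold lower) resembles ASNS closely, and which of the pair its reads came from is uncertain.

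The lists of serine, glycine and one-carbon enzymes, of MYC activity and ribosome biogenesis and of the G1 to S transition also passed downwards with AKB. Of 23 genes for serine, glycine and one-carbon enzymes 5 fell (9 adjusted over the list alone), among them PHGDH, the first enzyme of serine synthesis (1.5-fold), and the mitochondrial folate enzymes ALDH1L2 (1.54-fold) and MTHFD1L (1.34-fold) (list median −0.13, camera adjusted p = 9.83e-10). The 18 members outside the ATF4 list had a median of −0.099, with 1 that fell. As a set these 18 still ranked lower than other genes (unadjusted camera p = 1.93e-05, and 0.00125 with an estimated correlation). Of 36 genes of MYC activity and ribosome biogenesis 3 fell (12 over the list alone), including ornithine decarboxylase, ODC1 (536 ± 18.3 against 656 ± 13.3 CPM, adjusted p = 0.0113), RRP12 (1.28-fold) and UTP4 (1.18-fold), with a list median of −0.14 (camera adjusted p = 2.47e-10). MYC itself stood at 248 ± 19.5 against 238 ± 19.2 CPM (adjusted p = 0.871). Of 42 genes of the G1 to S transition 2 fell, the ribonucleotide reductase subunit RRM2 (1.24-fold, adjusted p = 0.0269) and cyclin E2, CCNE2 (1.4-fold) (2 over the list alone, median −0.085, camera adjusted p = 8.94e-05). These 3 lists passed the test with an estimated correlation too, each at an adjusted p of 0.00423. In the same order, 10, 14 and 4 of their members fell with the GC-content offset. Leaving out pyruvate replicates 3 and 4 gave 11, 15 and 8. The purine and pyrimidine list, with 1 of 29 lower (2 over the list alone), passed with the preset correlation (camera adjusted p = 0.0184, and adjusted p = 0.238 with an estimated correlation).

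TXNIP, an arrestin-domain protein that restrains glucose uptake and is transcribed by MondoA, fell from 202 ± 6.46 to 127 ± 6.19 CPM (log2 −0.67, SE 0.076, adjusted p = 0.00104), and its relative ARRDC4 fell 1.61-fold (adjusted p = 0.0135). They were the 2 of 13 MondoA and ChREBP targets that fell, and the list did not pass the test (1 rose and 2 fell over the list alone, camera adjusted p = 0.146). HERPUD1 (1.53-fold) and XBP1 (89.4 against 113 CPM), of the unfolded protein response (2 of 28 fell, 1 rose and 2 fell over the list alone, camera adjusted p = 0.786), the lymphocyte activation gene CD69 (1.9-fold), the transcription factor SOX5 (19 ± 0.66 against 32.5 ± 1.61 CPM) and RUNX1, a regulator of blood cell differentiation (1.24-fold), fell as well.

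The rises with AKB outnumbered the falls. ERBB3, a receptor of the epidermal growth factor receptor family, rose from 2.69 ± 0.377 to 8.21 ± 1.51 CPM (log2 1.61, SE 0.17, adjusted p = 0.000914), and apolipoprotein E, APOE, from 15.6 ± 1.76 to 38.5 ± 2.98 CPM (1.30, SE 0.16, adjusted p = 0.00192). LAPTM5, a lysosomal membrane protein of blood cells, rose 2.09-fold to 34.1 ± 1.91 CPM (adjusted p = 0.000923). Others among the 10 largest were the actin-binding protein CORO1A (2.34-fold), the synaptic vesicle gene SYNGR1 (2.24-fold), the ephrin EFNA1 (2.22-fold), the surface glycoprotein CD24 (2.2-fold), the protease inhibitor SPINT1 (2.16-fold) and TRANK1 (2.15-fold). FCGR2C, an Fc receptor gene (2.2-fold), has near-identical neighbours, so its reads are uncertain. Of the genes called, 98 higher and 26 lower differed at least 1.5-fold, and 28 and 4 at least 2-fold.

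Among metabolic genes, 4 of 28 for glycolysis and monocarboxylate transport rose with AKB and 0 fell (4 over the list alone), the neuronal enolase ENO2 (24.4 ± 1.32 against 13.9 ± 0.837 CPM, adjusted p = 0.000914), PFKFB4 (1.5-fold), aldolase C, ALDOC (1.27-fold), and pyruvate kinase, PKM (609 ± 25.3 against 500 ± 7.1 CPM). The list did not pass (camera adjusted p = 0.137). The lactate dehydrogenase genes LDHA (955 ± 35.2 against 994 ± 32.8 CPM, adjusted p = 0.835) and LDHB (743 against 740 CPM) and the monocarboxylate carrier SLC16A1 (343 against 354 CPM) had no call. In the NRF2 list the aldo-keto reductases AKR1C3 (19.2 ± 1.57 against 13 ± 1.08 CPM, adjusted p = 0.0142), AKR1C2 and AKR1C1 rose and SLC7A11 fell (4 and 2 over the list alone, camera adjusted p = 0.0582). AKR1C1 and AKR1C2 are near-identical, so the share of each is uncertain. Genes of lipid synthesis that rose were acetyl-CoA synthetase ACSS2 (132 ± 9.72 against 98.6 ± 1.86 CPM, adjusted p = 0.00917), ELOVL6 (1.35-fold) and FADS1 (1.2-fold), 3 of 20 in a list that did not pass (4 rose and 1 fell over the list alone, camera adjusted p = 0.0778). Of 34 HIF targets 4 rose, among them P4HA2 (1.51-fold), and 1 fell (6 and 2 over the list alone, camera adjusted p = 0.287), with PDK1 at 30.7 against 30.1 CPM (adjusted p = 0.943) and VEGFA at 94.8 against 114 CPM (adjusted p = 0.189). The isocitrate dehydrogenase gene IDH2 (1.45-fold) and the acyl-CoA dehydrogenase gene ACADSB (1.38-fold) rose.

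In 2 lists that passed the list test no member was called over all genes in the fit to all 12 libraries without the offset. Of 27 cholesterol synthesis genes 24 had estimates above 0 (median 0.090, camera adjusted p = 0.0184, and adjusted p = 0.0859 with an estimated correlation), with HMGCS1 at 748 against 586 CPM (adjusted p = 0.192). The edgeR test called 0 of them, where 5 were higher and 1 lower at an unadjusted p below 0.05 and DESeq2's Wald test called 1. Among these cholesterol genes 6 rose and 0 fell with the GC-content offset, and 5 rose and 1 fell with pyruvate replicates 3 and 4 left out. Of 17 interferon response genes 14 were above 0 (median 0.26, camera adjusted p = 0.00373, and adjusted p = 0.155 with an estimated correlation), with IFITM2 at 31.9 against 21.4 CPM (adjusted p = 0.0575). The edgeR test called 0 over all genes (1 over the list alone), where 7 were higher at an unadjusted p below 0.05 and DESeq2's Wald test called 1. Among these interferon genes 4 rose with the GC-content offset and 3 with pyruvate replicates 3 and 4 left out, and 0 fell in either fit. Embryonic globin, HBE1, rose from 2140 ± 71.1 to 2864 ± 118 CPM (1.34-fold, adjusted p = 0.00146), and its annotation overlaps that of HBG2. The erythroid list as a whole did not pass (2 rose and 1 fell of 39, also over the list alone, camera adjusted p = 0.413), nor did the megakaryocyte list, in which the integrin ITGA2B (1.84-fold) and the myosin light chain MYL9 (3.05-fold, 1.38 against 0.449 CPM) rose and RUNX1 fell (2 and 1 of 11, also over the list alone, camera adjusted p = 0.128).

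**Figure D2:**
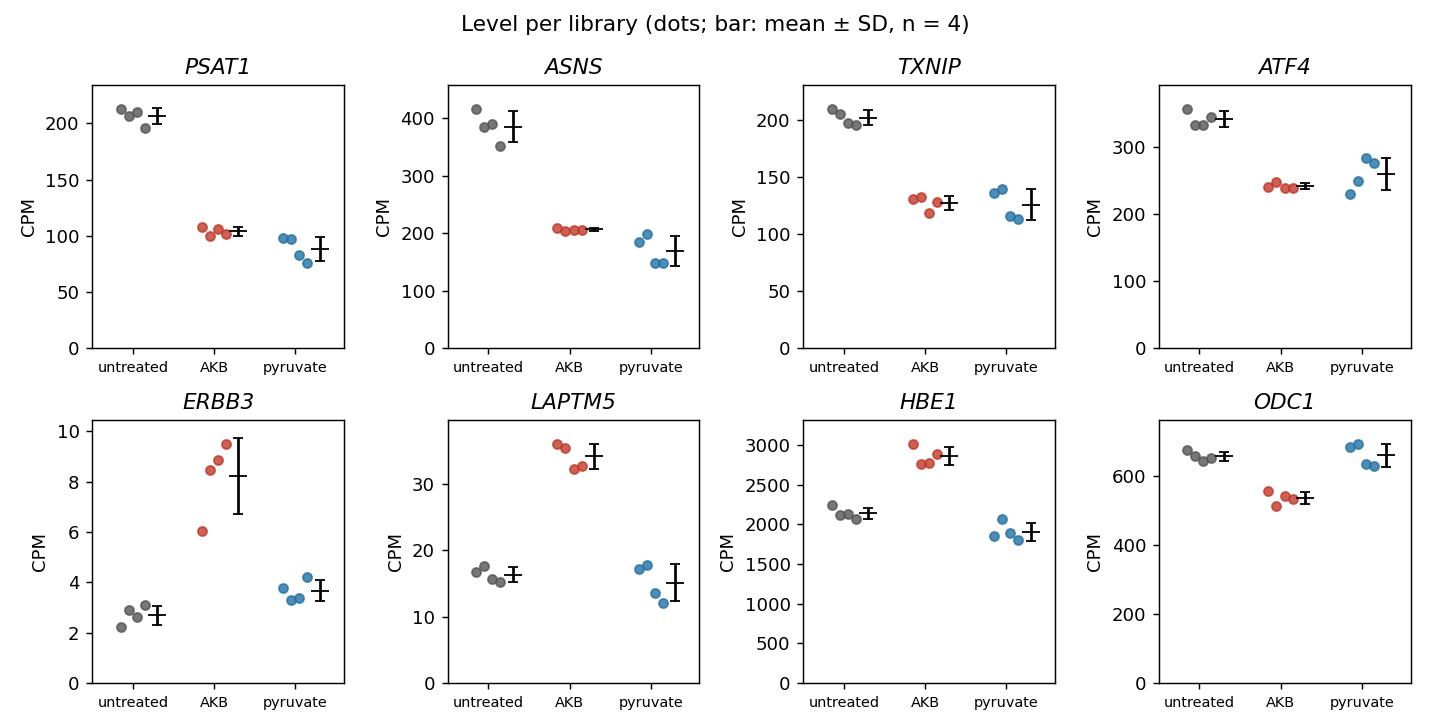
Level of 8 genes in each library (vertical axis, CPM) with mean ± SD by group. PSAT1, ASNS, TXNIP and ATF4 were lower in both treated groups, and ERBB3, LAPTM5 and HBE1 were higher with AKB than in the other groups.

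Amino acid response genes were also lower with pyruvate. PSAT1 fell from 206 ± 7.32 to 88.4 ± 10.8 CPM (log2 −1.22, SE 0.081, adjusted p = 3.41e-05), ASNS to 169 ± 26.1 CPM (−1.19, SE 0.096, adjusted p = 9.58e-05) and SLC7A11 from 103 ± 8.13 to 43.6 ± 8.4 CPM (−1.25, SE 0.12, adjusted p = 0.000366). ATF4 fell 1.32-fold to 259 ± 24.2 CPM (adjusted p = 0.0174). Of 36 members of the ATF4 list 22 fell and 0 rose (30 fell over the list alone). Of their estimates 34 were below 0, with a median of −0.48 (camera adjusted p = 1.71e-24, and 0.000123 with an estimated correlation). With the GC-content offset 750 genes were higher and 570 lower (132 and 113 of the first calls among them), and with pyruvate replicates 3 and 4 left out 21 and 78 (7 and 55), with 24 ATF4 list members lower (camera adjusted p = 2.85e-48). With the 8 libraries of this comparison alone 2 genes were higher and 14 lower.

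The fall in ALDH1L2 was 2.23-fold (16.4 ± 2.11 against 36.4 ± 2.37 CPM, adjusted p = 9.58e-05), in CTH 2.06-fold (15.3 ± 0.936 against 31.6 ± 1.98 CPM) and in CHAC1 2.06-fold (adjusted p = 0.0437, and 0.0515 without pyruvate replicates 3 and 4). CHAC1 was lower in pyruvate replicates 1 and 2 (4.09 and 3.07 CPM) than in replicates 3 and 4 (5.3 and 5.23 CPM), so its fall did not rest on the latter. ATF3 fell 1.78-fold, TRIB3 1.45-fold and DDIT4 1.92-fold, with a wide spread of DDIT4 in the pyruvate libraries (87.1 ± 29.2 CPM). The sterol synthesis enzyme FDFT1 (21.8 ± 4.17 against 44.2 ± 2.9 CPM, adjusted p = 0.0206) and CD69 (1.98-fold) were also among the 10 largest falls, as were ASNSP1 (2.59-fold) and the read-through gene DUS4L-BCAP29, whose reads may come from neighbouring genes. Of 23 serine, glycine and one-carbon enzyme genes 5 fell (9 fell and 1 rose over the list alone), among them PHGDH (1.67-fold) and MTHFD1L (1.31-fold) (median −0.17, camera adjusted p = 1.72e-05, and 0.0428 with an estimated correlation). The 18 members outside the ATF4 list had a median of −0.109, with 1 that fell (unadjusted camera p = 0.00593, and 0.0155 with an estimated correlation). DDIT3 (−0.15, adjusted p = 0.302) and GDF15 (−0.36, adjusted p = 0.179) had no call.

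TXNIP fell to 126 ± 13.5 CPM (log2 −0.69, SE 0.076, adjusted p = 0.00115), and ARRDC4 (1.47-fold) and the transcription factor KLF11 (log2 −0.44) were the other 2 of 13 MondoA and ChREBP targets that fell (5 over the list alone). This list did not pass the test (camera adjusted p = 0.172, and adjusted p = 0.462 with an estimated correlation) but at the preset correlation passed with the GC-content offset (0.00338) and with pyruvate replicates 3 and 4 left out (0.00165), where TXNIP kept its call (log2 −0.56, adjusted p = 0.000436) and ARRDC4 (0.146) and KLF11 (0.165) lost theirs. In pyruvate replicates 1 and 2 ARRDC4 still stood at 24.69 and 20.86 CPM against 28.63 to 36.42 CPM in untreated cells. KLF11 stood at 18.77 and 21.47 against 22.5 to 28.28 CPM. Of 39 erythroid genes 5 fell and 0 rose (13 and 4 over the list alone), including carbonic anhydrase 1, CA1 (12.5 ± 1.63 CPM, 1.64-fold), the fetal globins HBG2 (4117 ± 246 against 5195 ± 285 CPM, adjusted p = 0.0206) and HBG1 (2520 ± 160 against 3124 ± 222 CPM, adjusted p = 0.0489), the haem synthesis enzyme ALAS2 (1.25-fold) and the blood group gene RHD (1.35-fold). HBG1 and HBG2 are near-identical copies, and the share of each is uncertain. The list missed the threshold (camera adjusted p = 0.0561, and adjusted p = 0.399 with an estimated correlation) and at the preset correlation passed with the offset (4.49e-05) and without those libraries (9.15e-05). In the latter fit CA1 (adjusted p = 0.0269) and RHD (0.0442) kept their calls, and HBG2 (0.0846), HBG1 (0.204) and ALAS2 (0.0622) lost theirs. In pyruvate replicates 1 and 2 HBG2 still stood at 4280 and 4345 CPM against 4805 to 5456 CPM in untreated cells. HBG1 stood at 2530 and 2731 against 2842 to 3343 CPM, and ALAS2 at 55.66 and 65.96 against 73.65 to 83.89 CPM. RUNX1 (1.37-fold), XBP1 (1.37-fold) and HERPUD1 (1.51-fold) fell, and the unfolded protein response list, with 6 that rose and 2 that fell of 28 (2 and 2 without pyruvate replicates 3 and 4), did not pass (9 and 4 over the list alone, camera adjusted p = 0.483).

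The rises with pyruvate were largest in replicates 3 and 4. The 10 largest were the transcription cofactor SBNO2 (51.2 ± 21.3 against 11.7 ± 6.9 CPM, log2 2.13, SE 0.39, adjusted p = 0.0227), the chaperone CANX (28.3 ± 14.4 against 8.27 ± 2.43 CPM), the RNA-binding protein LSM7 (67 ± 41.9 against 19.8 ± 3.15 CPM), the ribosomal protein RPL36AL (2.87-fold), EDF1 (2.84-fold), OST4 (2.6-fold), the complex I subunit NDUFA13 (2.49-fold), TMSB10 (2.46-fold), PET100 (2.34-fold) and C11orf98 (2.29-fold). With replicates 3 and 4 left out, their log2 changes were 0.45 to 1.48. Of these 10, 9 lost their call and RPL36AL, which resembles RPL36A, kept it (log2 0.82, adjusted p = 0.0196). Of 78 cytosolic ribosomal protein genes 8 rose and 2 fell (31 and 7 over the list alone), with RPL11 at 764 ± 190 against 399 ± 45.8 CPM and RPS19 lower at 754 ± 20.4 against 879 ± 24 CPM (camera adjusted p = 0.00039, and adjusted p = 0.507 with an estimated correlation). Without those libraries 0 rose and 1 fell (camera adjusted p = 0.00674), and with the GC-content offset 22 rose and 4 fell (0.000212). Of 77 nuclear genes of oxidative phosphorylation 4 rose and 1 fell (23 and 4 over the list alone), among them NDUFS5 (194 ± 16.9 against 138 ± 9.93 CPM, adjusted p = 0.0109) and ATP5MF (1.89-fold) (camera adjusted p = 0.0012, and adjusted p = 0.507 with an estimated correlation). Without those libraries 1 rose and this list did not pass (0.084), while with the GC-content offset 19 rose and 2 fell (4.49e-05). Of 22 heat shock genes 2 rose, HSPE1 (log2 0.51) and STIP1 (0.52) (6 over the list alone, camera adjusted p = 0.0863, and adjusted p = 0.498 with an estimated correlation). At the preset correlation this list passed with the GC-content offset (0.000395) and with replicates 3 and 4 left out (0.000169), where HSPE1 (adjusted p = 0.0515) and STIP1 (0.14) lost their calls.

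Of 28 glycolysis and transport genes 4 rose with pyruvate and 0 fell (11 rose over the list alone), PKM (635 ± 40.2 against 500 ± 7.1 CPM, adjusted p = 0.0115), ALDOC (1.31-fold), GAPDH (2217 ± 234 against 1780 ± 74.1 CPM, adjusted p = 0.0406) and GPI (1.35-fold) (camera adjusted p = 0.000503, and adjusted p = 0.462 with an estimated correlation). PKM alone kept its call without replicates 3 and 4 (log2 0.29, adjusted p = 0.0326), where ALDOC stood at an adjusted p of 0.0544 and the list passed (camera adjusted p = 0.000428). LDHA (968 ± 131 CPM, adjusted p = 0.758), LDHB (−0.04, adjusted p = 0.747), SLC16A1 (−0.27, adjusted p = 0.125), PDK1 (−0.23, adjusted p = 0.132), VEGFA (−0.22, adjusted p = 0.132), HMGCS1 (−0.22, adjusted p = 0.23) and MYC (0.13, adjusted p = 0.378) had no call. Of the pyruvate calls, 71 higher and 46 lower differed at least 1.5-fold, and 24 and 14 at least 2-fold.

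Genes of the amino acid response were among those lower with both acceptors. Of 42 genes lower with both, 21 belonged to the ATF4 list. Of the list's other members, GPT2 was called with pyruvate alone and SLC7A5 with AKB alone. Outside the list TXNIP, ARRDC4, RUNX1, XBP1, HERPUD1, CD69 and the complex I subunit NDUFB2 fell with both. So did the histone H1-2, from a list fixed as a check of RNA selection. The mean log2 CPM of the ATF4 list was 6.654 ± 0.017 in untreated cells, 6.107 ± 0.034 with AKB and 6.087 ± 0.081 with pyruvate, differences of −0.55 and −0.57 (two-sided exact permutation p = 0.0286 for each, the smallest possible). Higher with both were 13 genes, including PKM, ALDOC, the lysosomal protease CTSB, the spermine oxidase SMOX and the transcription regulator HEXIM1. The edgeR test called 0 genes in opposite directions, and DESeq2's Wald test 5. At an unadjusted p below 0.05 in each comparison 45 genes were opposite and 630 in the same direction. Shared untreated libraries alone favour the same direction. Among all genes 67.8% had the same sign, against 66.5% on average in the simulations in which no group changed. No simulated counterpart of the 45 and 630 was made, so they do not measure how alike the acceptors act. The offset gave 77 genes higher and 181 lower with both and 11 opposite, and with pyruvate replicates 3 and 4 left out 5 and 60.

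Sharing the untreated libraries alone ties these fold changes. Across genes the Pearson correlation was 0.546, against a mean of 0.492 and a highest of 0.563 in 20 simulations in which no group changed, and 0.216 on average (0.156 to 0.26) with the controls split. The covariance was 0.109 against a simulated mean of 0.0451 (highest 0.0571), and 0.112 (0.0844 to 0.132) with split controls. The genes kept differed, 13598 in the data, 13299 on average in the simulations and 14159 with split controls, so these values are not strictly alike. The simulations also gave all groups the same spread per gene and held no GC trend. Independent lists of these sizes would share 1.9 higher and 0.76 lower genes. The simulations shared 0, but they called only 0.05 genes per comparison on average (highest 1). That 0 was therefore fixed in advance and does not measure the overlap that shared controls could give. With split controls, which leave 2 untreated libraries per comparison, 1 gene was higher and 11.7 lower with both on average (9 to 16 lower), and the ATF4 list kept medians of −0.504 to −0.494 with AKB and −0.487 to −0.463 with pyruvate.

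**Figure D3:**
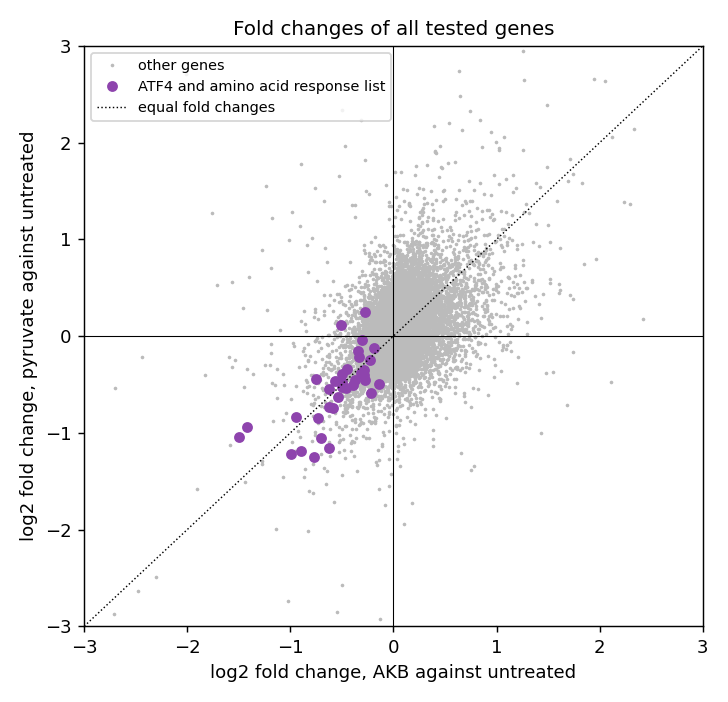
Log2 fold change with AKB (horizontal axis) and with pyruvate (vertical axis) against untreated cells for the genes tested, limited to 3 either way, which leaves 37 genes outside. Of the 36 ATF4 list members (coloured) 36 lay below 0 with AKB and 34 with pyruvate, with medians of −0.50 and −0.48.

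Compared directly, AKB and pyruvate differed in 426 genes, 264 higher and 162 lower with AKB. LAPTM5 stood at 34.1 ± 1.91 CPM with AKB and 15.1 ± 2.77 with pyruvate (log2 1.18, 95% interval 0.92 to 1.44, adjusted p = 0.00123), and ERBB3 at 8.21 ± 1.51 against 3.67 ± 0.412 CPM (1.16, 0.80 to 1.52, adjusted p = 0.00799). HBE1 stood at 2864 ± 118 against 1904 ± 116 CPM (0.59, 0.48 to 0.70, adjusted p = 0.00072). With the GC-content offset 1016 genes were higher and 955 lower (252 and 153 of the first calls among them), and with pyruvate replicates 3 and 4 left out 351 and 257 (155 and 60). With the 8 libraries of this comparison alone 6 were higher and 0 lower, where edgeR's unadjusted p was below 0.05 for 1380 genes lower with AKB, and DESeq2's Wald test on all libraries called 891. The share of called genes that were higher with AKB was 62.0%, with 77.0% for library size alone, 53.6% for DESeq2's size factors and 51.5% for the offset. It fell below 50% with DESeq2's Wald test (41.7%), with the GC-content offset and the replicate block (49.8%), without pyruvate replicate 1 (46.5%) and without pyruvate replicate 2 (43.7%).

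The progestin receptor gene PAQR8 (8.71 ± 1.24 against 3.55 ± 0.564 CPM, adjusted p = 0.00613) and UBE2L6, an enzyme that conjugates ISG15 (2.3-fold), were also among the 5 largest rises, as was the sulfotransferase SULT1A4 (3.76-fold, adjusted p = 0.0457), which has a near-identical copy and spread widely (5.52 ± 4.2 CPM). Of 39 erythroid genes 6 were higher and 1 lower with AKB (18 and 5 over the list alone), including HBE1, CA1 (1.74-fold), RHD (1.42-fold) and HBG2 (5315 ± 357 against 4117 ± 246 CPM, adjusted p = 0.0108) (camera adjusted p = 0.00715, and adjusted p = 0.1 with an estimated correlation). Of 11 megakaryocyte genes 1 was higher, the tubulin TUBB1 (1.25-fold; 4 over the list alone) (camera adjusted p = 0.0167, and adjusted p = 0.1 with an estimated correlation). ENO2 (log2 0.65, 95% interval 0.46 to 0.84), AKR1C3 (0.91, 0.69 to 1.13), ELOVL6 (1.56-fold), ACSS2 (1.29-fold) and HMGCS1 (0.57, 0.31 to 0.82, adjusted p = 0.0297) were higher with AKB. The NRF2 list, with 3 of 27 higher (5 higher and 1 lower over the list alone), missed the threshold (camera adjusted p = 0.0529, and adjusted p = 0.36 with an estimated correlation) and at the preset correlation passed with the GC-content offset (0.0162) and with pyruvate replicates 3 and 4 left out (0.0291). Relative to both other groups, 95 genes were higher and 13 lower with AKB, and 40 higher and 28 lower with pyruvate.

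The lists of MYC activity and ribosome biogenesis and of the G1 to S transition passed as lower with AKB than with pyruvate. Of 36 genes of MYC activity and ribosome biogenesis 11 were lower and 0 higher (22 over the list alone), among them ODC1 (536 ± 18.3 against 659 ± 33.4 CPM, log2 −0.30, 95% interval −0.41 to −0.19, adjusted p = 0.0109), nucleolin, NCL (1.23-fold), RRP9 (1.42-fold) and NOP2 (1.38-fold), and 35 estimates were below 0 (camera adjusted p = 1.57e-11, and 0.00661 with an estimated correlation). Of 42 G1 to S genes 1 was lower, thymidylate synthase, TYMS (1.19-fold; 2 over the list alone) (camera adjusted p = 0.0011, and 0.0221 with an estimated correlation). The 5 largest falls, LSM7, CANX, RPL36AL, the endosomal gene RABEP2 (1.87-fold) and the mitochondrial import gene TIMM13 (1.75-fold), were smaller without pyruvate replicates 3 and 4. The log2 differences were then −0.42, −0.63, −0.54, −0.56 and −0.35, of which that of TIMM13 kept its call (adjusted p = 0.0191).

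At the preset correlation, and not with an estimated one, 5 further lists were lower with AKB than with pyruvate. One was oxidative phosphorylation (3 of 77 lower, 15 over the list alone, such as UQCR10 at log2 −0.47, camera adjusted p = 3.03e-07, and adjusted p = 0.221 with an estimated correlation). Another was heat shock (2 of 22 lower, 4 over the list alone, HSPE1 at 1.44-fold and DNAJB1 at 1.21-fold, camera adjusted p = 0.00394, and adjusted p = 0.126 with an estimated correlation). Glycolysis also passed (1 higher and 2 lower of 28, 3 and 8 over the list alone, with ENO1 1.17-fold lower, camera adjusted p = 0.049, and adjusted p = 0.506 with an estimated correlation). The others were the cytosolic ribosomal proteins (78 tested, 5 lower over the list alone, camera adjusted p = 0.0011, and adjusted p = 0.493 with an estimated correlation) and the replication-dependent histones (38 tested, 2 lower over the list alone, camera adjusted p = 0.0127, and adjusted p = 0.0696 with an estimated correlation). Over all genes edgeR called 0 members of either. At an unadjusted p below 0.05, 26 ribosomal protein genes were lower and 3 higher and 8 histone genes lower and 1 higher. DESeq2's Wald test called 17 and 3 of them lower. The histone list was fixed as a check of RNA selection, and in these poly(A)-selected libraries its levels may reflect that selection. With pyruvate replicates 3 and 4 left out, the glycolysis (0.395), ribosomal protein (0.217) and histone (0.0699) lists no longer passed, and with the GC-content offset the glycolysis list did not (0.302).

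In the amino acid response the direct comparison separated few genes. Of 36 ATF4 list members 2 were higher with AKB, ALDH1L2 (log2 0.53, 95% interval 0.33 to 0.74, adjusted p = 0.0159) and CTH (0.34, 0.17 to 0.52, adjusted p = 0.0461), 3 when adjusted over the list alone, and the list did not pass (median 0.047, camera adjusted p = 0.786). The interval lay within 0.5 log2 either way for 24 of the 36 and within 1 for 34. These intervals rest on the spread shared by the 3 groups. The pyruvate libraries varied more (SD of the list's mean log2 CPM 0.081 against 0.034 with AKB), so the intervals may be too narrow. Differences that missed the threshold were ATF4 (−0.10, −0.25 to 0.04), TRIB3 (0.08, −0.08 to 0.24), PSAT1 (0.23, 0.06 to 0.41), ASNS (0.29, 0.08 to 0.49), SLC7A11 (0.48, 0.22 to 0.73, adjusted p = 0.0503) and CHAC1 (−0.45, −0.96 to 0.06). Outside it TXNIP (0.02, −0.15 to 0.18), ARRDC4 (−0.13, −0.39 to 0.13), LDHA (−0.02, −0.19 to 0.16), MYC (−0.07, −0.28 to 0.14), HBG1 (0.24, 0.08 to 0.39) and ALAS2 (0.26, 0.11 to 0.41) had no call. A p that misses the threshold does not show that the acceptors act alike.

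**Figure D4:**
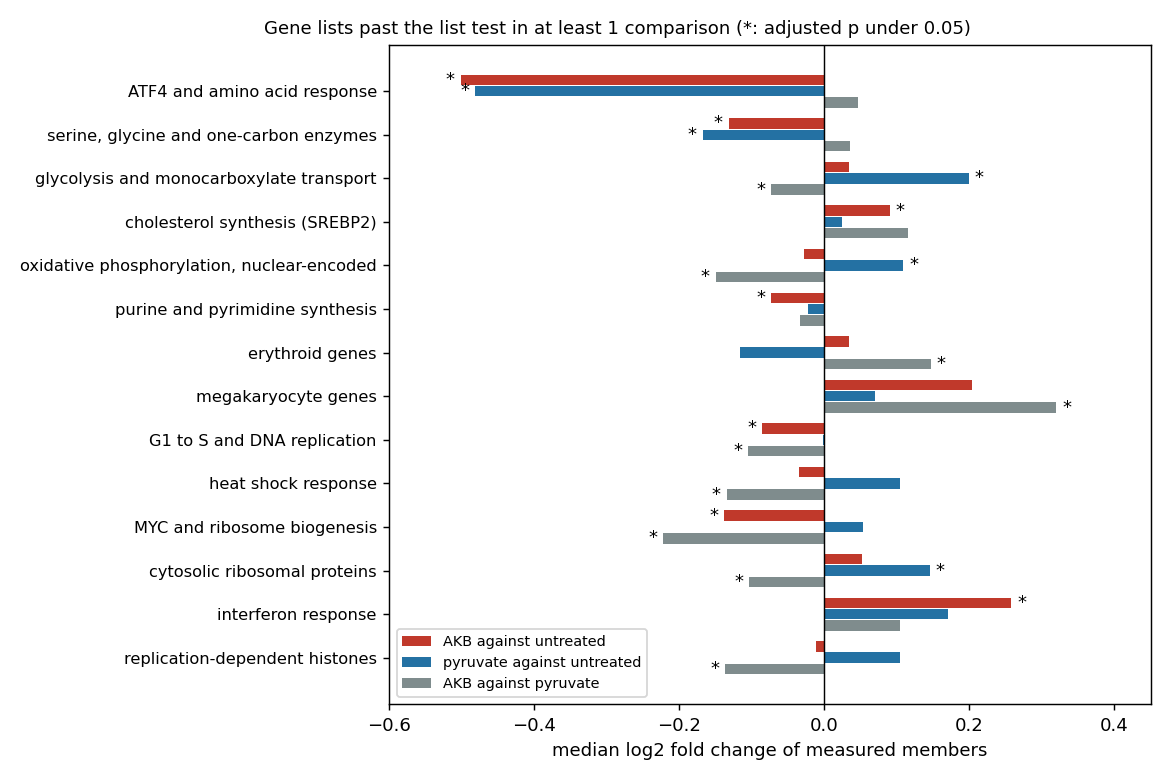
Median log2 fold change (horizontal axis) of each gene list that passed the list test in at least 1 comparison, with an asterisk at a camera adjusted p below 0.05. The ATF4 list stood at −0.50 with AKB and −0.48 with pyruvate against untreated cells and at 0.047 between them.

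The genes described lie at PSAT1 (ENSG00000135069, chromosome 9, 78297143 to 78330093), ASNS (ENSG00000070669, chromosome 7, 97852118 to 97872542), CHAC1 (ENSG00000128965, chromosome 15, 40952962 to 40956519), DDIT4 (ENSG00000168209, chromosome 10, 72273920 to 72276036), ATF4 (ENSG00000128272, chromosome 22, 39519695 to 39522685) and TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600). SLC7A11 is ENSG00000151012 (chromosome 4, 138164097 to 138242349), ERBB3 ENSG00000065361 (chromosome 12, 56076799 to 56103505), LAPTM5 ENSG00000162511 (chromosome 1, 30732469 to 30757820), APOE ENSG00000130203 (chromosome 19, 44905754 to 44909393), HBE1 ENSG00000213931 (chromosome 11, 5268345 to 5505652) and ODC1 ENSG00000115758 (chromosome 2, 10439968 to 10448504). Positions are on GRCh38 in GENCODE 29.

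In the tables that the authors deposited from DESeq2, 354 genes were higher and 280 lower with AKB than in untreated cells, 875 and 598 with pyruvate, and 544 higher and 722 lower with AKB than with pyruvate (the authors' adjusted p below 0.05, among 12945, 12261 and 12604 genes with one). Of the edgeR calls with a deposited adjusted p, 210 of 266, 232 of 262 and 317 of 416 were also called there in the same direction, and log2 fold changes of all genes had Pearson correlations of 0.869, 0.851 and 0.877. The authors' log2 change with AKB was −0.98 for PSAT1 (DESeq2 adjusted p = 1.3e-42), −0.92 for ASNS (8.24e-07), −0.68 for TXNIP (1.77e-12), 1.07 for LAPTM5 (1.18e-15) and 1.12 for ERBB3 (0.0339). Among the genes called here, SPINT1 (0.24, DESeq2 adjusted p = 0.806), FADS1 (0.17, 0.514), ELOVL6 (0.37, 0.157), RRM2 (−0.26, 0.122), MYL9 (1.59, 0.0737), AKR1C1 (0.29, 0.0686) and ACADSB (0.48, 0.0599) were not called there with AKB. With pyruvate KLF11 (−0.24, 0.311) and RHD (−0.32, 0.07) were not, nor between the acceptors NCL (−0.22, 0.074), DNAJB1 (−0.19, 0.359), ACADSB (0.24, 0.398) and SLC40A1 (0.09, 0.628). Conversely, some genes without a call here with AKB were called there. They included HMGCS1 (0.36, DESeq2 adjusted p = 8.57e-06), VEGFA (−0.32, 0.00143), BCAT1 (−0.44, 0.00766) and DDIT3 (−0.34, 0.0414).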

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

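The test of GC content for pyruvate replicates 3 and 4, the test of megakaryocyte and erythroid genes together, the removal of each library's GC trend, and the GC-content offset were chosen after the results were seen. In 9 of 225 groups of 4 libraries a single library stood far from the other 3, by Dixon's ratio of the gap to the range, over 75 values. Chance gives about 1 in 20 groups, so that this number is no more than chance gives.

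In AKB replicate 1, 5 of the 9 were found. HBG1 stood at 3370 CPM against 2830 to 2850 in the other AKB libraries, HBG2 at 5840 against 5080 to 5210, the summed erythroid list at 23400 against 21600 to 21900, EFNA1 at 8.04 against 5.43 to 5.68 and EDF1 at 22 against 29.6 to 30.7. The globins hold much of the erythroid sum, so these values are not independent. In pyruvate replicate 1, INHBE stood at 3.91 CPM against 5.1 to 5.23 and the summed G1 to S list at 7030 against 7300 to 7330. In untreated cells DDIT3 stood at 25.1 CPM in replicate 1 against 23.5 to 23.6, and LDHA at 944 in replicate 4 against 1010.

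Pyruvate replicates 3 and 4 stood apart from replicates 1 and 2 with a Spearman correlation of 0.857 between the difference and transcript GC over 9301 genes, which a GC content bias between these libraries needs. After thinning to the smallest total, 15353200 counts, the median absolute log2 difference of 4710 genes was 0.326 against 0.339 (ratio 0.962), but thinning could not have halved it at these levels, so sequencing depth stays open, although untreated replicates 1 and 3, the next deepest (18.1e6 and 18.4e6 counts), had Spearman correlations with GC of −0.633 and −0.626. The ATF4 list stood at −0.528 in replicates 3 and 4 and −0.603 in replicates 1 and 2 (difference 0.075), and with the GC trend of each library removed at −0.614 and −0.59 (difference −0.0238). As the first test left out GC content, which runs higher in this list than in all genes, a stronger response to pyruvate in replicates 3 and 4 cannot be told apart from none, with PSAT1 (82.8 and 75.9 against 97.7 and 97.3 CPM) and ASNS (147 and 147 against 184 and 199 CPM) lower in them and DDIT4 (114 and 110 against 65.7 and 58.3 CPM), ATF4 (282 and 276 against 230 and 249 CPM), CHAC1 and TRIB3 higher. A difference in library preparation or RNA between these libraries may be the source, and no label gives one.

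The 95 genes higher with AKB than in both other groups had a median log2 change of 0.588 against untreated cells and of 0.59 with the GC-content offset (ratio 1). Their median GC content was 50.3% against 48.1% for all tested genes, so the offset had little room to reduce this median. The values argue only against a smooth trend along transcript GC content as the source. The summed CPM of 8 monocyte and granulocyte markers was 1.43 times that of untreated cells, almost all of it LYZ (47.2 against 33.4 CPM), with the other 7 at 2.52 CPM or less in every group. As 1 marker carries the sum, a share of another blood cell type and a rise of LYZ in K562 cells cannot be told apart. A move towards erythroid and megakaryocyte genes together would raise both lists. The medians were 0.0346 for the erythroid and 0.204 for the megakaryocyte list, but erythroid genes went both ways (22 above 0 and 17 below), so this stays open.

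The ATF4 list was lower with AKB and with pyruvate, with a mean of the medians of −0.492. With the GC-content offset it was −0.55 (ratio 1.12). The median GC content of the list was 51.8% against 48.1% for all tested genes, so the offset had little room to reduce the medians. The values argue only against a smooth trend along transcript GC content as the cause. In 6 of 6 ways of splitting the untreated libraries both medians stayed below 0. Relative to the untreated mean, the list's median was −0.0242 to 0.0277 in the untreated libraries and −0.628 to −0.453 in the treated ones. With values so far apart, no split could have brought a median to 0. The values show only that no single untreated library carried the difference. A shift common to all untreated libraries would stay in every split, so the test cannot decide whether the shared untreated libraries were the cause. A response to the acceptors stays open as a hypothesis, and since the labels give neither culture nor batch, a difference between cultures was not tested.

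Among the 35 splits of 8 libraries into 4 and 4, the real one gave 268 genes for AKB against untreated, where the highest other gave 1, and 426 for AKB against pyruvate, where the highest other gave 2. In each case 1 split, the real one, gave as many, the lowest share that 35 splits allow, which argues against a chance division of these libraries. The other splits mix the groups, which widens the spread within them and lowers their counts. Chance differences between cultures are not covered by this test. With the GC-content offset the same held for pyruvate against untreated (1320, highest other 2, 1 split) and for AKB against pyruvate (1971, highest other 2, 1 split). Without the offset chance cannot be excluded for pyruvate against untreated, as 2 splits gave at least its 265 genes. The other split, pyruvate replicates 1, 3 and 4 with untreated replicate 4 against the rest, gave 1522 genes, which points to a structure of the samples, and gave 2 with the offset. For the numbers of lists chance cannot be excluded, as 5 splits gave at least the 7 of AKB against untreated (highest other 8), 8 the 5 of pyruvate against untreated (10) and 4 the 9 of AKB against pyruvate (11). For AKB against untreated the 4 other splits each kept 3 of the 4 AKB libraries together, and so part of the real contrast, while splits with 2 and 2 gave at most 3 lists. This did not hold elsewhere. Splits with 2 and 2 gave up to 6 lists for pyruvate against untreated, above the real 5, and up to 8 for AKB against pyruvate, near the real 9.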

How the results depend on the processing

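The GC-content offset, the fit with pyruvate replicates 3 and 4 left out and the GC-content offset with the replicate block were chosen after the data were examined. The counts of genes past the threshold moved widely while no call of a named gene changed its direction, and the median log2 change of all genes moved by less than 0.1 under every setting. For AKB against untreated 24 of 34 called named genes were called under every alternative, for pyruvate against untreated 7 of 40 and for AKB against pyruvate 2 of 29. With pyruvate replicates 3 and 4 left out 0, 24 and 12 lost the call, and with the 8 libraries compared alone 0, 32 and 27. The ATF4 and serine lists passed under every list alternative in both comparisons with untreated cells. The MYC and ribosome biogenesis and G1 to S lists did so in AKB against untreated and AKB against pyruvate. The list of G2 and mitosis, with no call at first, changed its direction with pyruvate replicates 3 and 4 left out and passed at the preset correlation (camera adjusted p = 0.000941 upwards for pyruvate against untreated and 0.0278 downwards for AKB against pyruvate). With all libraries and an estimated correlation its camera adjusted p was 0.964 and 0.859 in these comparisons. At a depth of 15353200 to 21301073 counts genes of low level, such as MYL9 at 0.449 CPM and ERBB3 at 2.69 CPM in untreated cells, rest on few reads. In the simulated data 60 of 100 changes of 1.5-fold were recovered in either comparison with untreated cells.

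Numbers of genes are given in the order higher and lower with AKB than untreated (186 and 82), higher and lower with pyruvate than untreated (139 and 126), and higher and lower with AKB than with pyruvate (264 and 162). With the GC-content offset they were 667 and 475, 750 and 570, and 1016 and 955. With pyruvate replicates 3 and 4 left out they were 677 and 601, 21 and 78, and 351 and 257. With the GC-content offset and the replicate block they were 545 and 396, 815 and 613, and 977 and 984. With DESeq2's Wald test, which gave 17.8% false calls on simulated data, they were 335 and 196, 1086 and 738, and 636 and 891. With the 8 libraries compared alone they were 709 and 630, 2 and 14, and 6 and 0; the fit then no longer shares the spread of the pyruvate libraries with AKB against untreated. With the test against a fold change of 1.2, which is stricter by construction, they were 29 and 16, 1 and 9, and 16 and 1. With the replicate block they were 111 and 47, 306 and 259, and 214 and 142. Residuals of libraries with the same number had correlations of −0.17 to 0.31 for AKB and untreated, −0.14 to 0.52 for pyruvate and untreated and −0.22 to 0.26 for AKB and pyruvate, so the number is not shown to mark pairs. With no filter the last 4 counts fell to 73 and 79, and 145 and 69. With limma-voom 90 were higher with pyruvate than untreated, and with library size alone 93 were lower with AKB than with pyruvate. The cause was not tested except where named.

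Leaving out 1 library at a time gave 57 to 250 higher and 34 to 107 lower for AKB against untreated. The counts fell most without an untreated or an AKB library (57 to 103 higher and 34 to 56 lower). For pyruvate against untreated the range was 1 to 1931 higher and 31 to 1680 lower. It was 1407 and 1224 without pyruvate replicate 1, 1931 and 1680 without pyruvate replicate 2, and 3 and 44 without pyruvate replicate 3 or 4. Without untreated replicates 1, 2 and 3 it was 2, 1 and 1 higher and 31, 31 and 33 lower, without untreated replicate 4 it was 87 and 88, and without an AKB library 26 to 47 and 58 to 72. For AKB against pyruvate it was 61 to 922 higher and 7 to 1189 lower, with 823 and 947 without pyruvate replicate 1, 922 and 1189 without pyruvate replicate 2, 97 and 15 without pyruvate replicate 3, 101 and 22 without pyruvate replicate 4, 61 to 106 and 7 to 21 without an AKB library and 138 to 158 and 34 to 59 without an untreated one. Lists past the threshold numbered 6 to 11, 5 to 8 and 5 to 10. The genes changed in the same direction by both acceptors numbered 23 to 142 (highest without pyruvate replicate 2, lowest without untreated replicate 3), and the correlation of fold changes was 0.416 (without AKB replicate 3) to 0.682 (without untreated replicate 4). The genes higher with AKB than in both other groups, 95, numbered 23 to 126, 420 with the GC-content offset (92 of the 95 among them) and 232 with pyruvate replicates 3 and 4 left out (77 among them).

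The 55 genes changed in the same direction became 153 with DESeq2's Wald test and 258 with the GC-content offset, and 11, 10, 15, 10, 17 and 13 in the 6 splits of the untreated libraries, which leave fewer libraries. The correlation of 0.546 became 0.387 with pyruvate replicates 3 and 4 left out, and 0.26, 0.249, 0.226, 0.216, 0.156 and 0.191 in those splits. Of lists, 7, 5 and 9 passed with the preset correlation, 4, 2 and 2 with an estimated correlation and 14, 8 and 11 with fry. With no filter 11 passed for AKB against untreated, and for pyruvate against untreated 9 passed with the GC-content offset and 9 with pyruvate replicates 3 and 4 left out. The genes shared with the authors' calls, 210, 232 and 317, became 374, 1013 and 887 with DESeq2's Wald test in place of edgeR. The share of higher genes was 69.4%, 52.5% and 62.0%. For AKB against untreated it was 58.4% with the GC-content offset, 53% with pyruvate replicates 3 and 4 left out and 52.9% with the 8 libraries alone. For pyruvate against untreated it was 40.9% with limma-voom and 21.2% with pyruvate replicates 3 and 4 left out, and for AKB against pyruvate 41.7% with DESeq2's Wald test.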

Other observations

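The GC-content offset and the fit with pyruvate replicates 3 and 4 left out were chosen after the data were examined. AKB is oxidised through propionyl-CoA, and the list of the branched-chain ketoacid and propionate pathway did not pass with AKB (1 of 29 rose and 1 fell, also over the list alone, camera adjusted p = 0.413) or with pyruvate (1 rose and 2 fell, also over the list alone, 0.708). ACADSB, an acyl-CoA dehydrogenase of isoleucine breakdown, rose with AKB (29.6 ± 0.871 against 21.5 ± 1.4 CPM, log2 0.46, adjusted p = 0.00917) and stood above its level with pyruvate (0.34, 95% interval 0.18 to 0.50, adjusted p = 0.0369). BCAT1, the cytosolic branched-chain aminotransferase, fell with pyruvate (337 ± 77.4 against 507 ± 35.3 CPM, adjusted p = 0.045, and 0.0564 with pyruvate replicates 3 and 4 left out) and stood at 408 ± 22.6 CPM with AKB (adjusted p = 0.321). The list of 27 genes of NAD metabolism and NADH shuttles did not pass with AKB (camera adjusted p = 0.199) or with pyruvate (0.331, and 0.498 with an estimated correlation). At the preset correlation it passed with pyruvate when the GC-content offset was used (camera adjusted p = 0.0442). The aspartate aminotransferase GOT1 stood at 78.5 ± 3.91 against 84.6 ± 3.64 CPM with AKB (adjusted p = 0.539), and the glycerol phosphate dehydrogenase GPD2 at 41.3 ± 6.63 against 51.4 ± 2.77 CPM with pyruvate (adjusted p = 0.0915).

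In the citric acid cycle list IDH2 rose with AKB (69.1 ± 3.02 against 47.7 ± 2.25 CPM, adjusted p = 0.00854). The list passed with neither AKB (camera adjusted p = 0.473) nor pyruvate (0.962). Among 13 mRNAs of mitochondrial DNA, MT-ND5 rose with pyruvate (2555 ± 281 against 1668 ± 206 CPM, adjusted p = 0.0206, and 0.0901 with pyruvate replicates 3 and 4 left out), the 1 called over all genes (2 over the list alone, camera adjusted p = 0.33). Of 22 genes of iron handling 2 were higher with AKB than with pyruvate (5 higher and 1 lower over the list alone), the ferroportin gene SLC40A1 at 86.2 ± 5.21 against 66.9 ± 8.3 CPM (adjusted p = 0.045) and the mitochondrial carrier SLC25A37 at 362 ± 8.69 against 310 ± 12.1 CPM (adjusted p = 0.0406), which the erythroid list also holds. The iron list did not pass (median 0.0109, camera adjusted p = 0.974). The epithelial adhesion gene EPCAM, in a list of other cell types with too few members to test, stood at 96.8, 94.1 and 93.4 CPM in untreated cells, with AKB and with pyruvate. The lists of fibroblast, lymphocyte, and monocyte and granulocyte markers had 4, 2 and 3 members tested, with medians of 0.357, 0.654 and 0.62 with AKB against untreated. LYZ rose with AKB (adjusted p = 0.0308), and over each list alone 1, 2 and 3 members were higher.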
